A study of Mus musculus with 2 samples.

How the data were processed

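Single-cell RNA was measured in liver immune cells of wild-type, specific pathogen-free mice that drank control water or metronidazole water for 3 weeks. Each group is 1 library, made from the pooled sorted cells of 3 mice. Per the labels, livers were perfused and dissociated, CD45-positive cells were enriched on magnetic beads, stained, fixed and sorted as Aqua-negative and CD45-positive, and the libraries were made with the 10x Genomics Fixed RNA Profiling kit. In this assay probe pairs are hybridised to RNA in fixed cells, and samples get a barcode each before they are pooled and loaded. The labels speak of 1 further sample prepared with these, which is not among the deposited libraries and was not analysed here. The dose of metronidazole and the sex and age of the mice are not given in the sources used here.

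The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell, as whole numbers without normalization. The other deposited files are lists of cell barcodes and of gene names, whose unit is other than a measurement. The submitters' processing notes name Cell Ranger 7.1.0, Seurat 5.3.0 and the builds mm10 and GRCm38 without stating what each was used for. Empty droplets had been left out before deposit, so free RNA could not be estimated from them, and the lowest total of a deposited cell was 495 UMIs in both libraries. The files list 19059 genes, of which 19048 (99.9%) were found by their Ensembl ID in the GENCODE vM21 annotation of GRCm38, the source of the coordinates. The control library held 13240480 UMIs in 5648 cells and the metronidazole library 11027437 UMIs in 6012 cells. No UMI was seen for 4471 genes in the control library and for 4831 genes in the metronidazole library.

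Cells with at least 300 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, which left out 21 control and 11 metronidazole cells. Doublets were called in each library with Scrublet at an expected rate of 0.06 and left out. Scrublet marked 0 control and 2 metronidazole cells, 0.0172% of 11660 cells, so the caller did not work on these data. Clusters whose median doublet score was over 3 times that of all cells were therefore kept unnamed, a threshold chosen after the scores were seen. This left clusters 9, 11 and 20 unnamed, but counted in every total. The 5627 control and 5999 metronidazole cells kept were scaled to 10000 counts per cell and log-transformed. Both libraries were clustered together with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0) without batch correction. Each cluster was named by the highest score among 27 sets of marker genes, with at least 3 markers of the set detected at 20 CPM (UMIs of a gene per 1000000 UMIs of the cluster or class), so names have the form "Kupffer-like". Several names are less sure because the best scores were close. Cluster 2 scored 2.35 as NKT cell and 2.28 as CD4 T cell, and cluster 19 scored 1.04 as Kupffer cell and 0.89 as hepatocyte. Cluster 3 scored 2.08 as NKT cell and 1.82 as type 1 innate lymphoid cell, and cluster 12 scored 1.51 as classical monocyte and 1.17 as monocyte-derived macrophage.

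For each class with at least 100 cells in both libraries, UMIs were summed per library and given as CPM of the class total, with exact Poisson intervals. The log2 fold is that of metronidazole over control CPM after adding 5 CPM to both. Fold intervals are exact conditional intervals of the ratio without added counts. Shares of cells have exact Clopper-Pearson intervals. All intervals are at the 95% level. With 1 library per group, no test between groups and no count of changed genes was made, since cells of 1 pool are not replicates.

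Of 30 gene lists, the 29 described were Kupffer cell identity, efferocytosis and scavenger receptors, microbe capture, bacterial sensing, NF-kB inflammatory cytokines and targets, type I interferon response, interferon-gamma response, MHC class II presentation, MHC class I presentation, alternative activation and tolerance, lipid-associated macrophage, LXR targets and cholesterol efflux, cholesterol biosynthesis, iron and heme handling, complement components, bile acid, aryl hydrocarbon and short-chain fatty acid receptors, glycolysis, oxidative phosphorylation, lysosome, NRF2 and oxidative stress, chemokines and chemokine receptors, cytotoxic and effector lymphocyte, naive and central memory lymphocyte, neutrophil maturity, immediate early and heat shock, cell cycle, hepatocyte, endothelial and stellate, and sex-linked transcripts. The 30 lists hold 516 genes, and some genes stand in more than 1 list. Of the genes in the lists and the marker sets together, 15 are not in the probe set (Aldoa, Atp5h, Ccnb1, Clec7a, Cx3cr1, Eno1, Ftl1, Gapdh, Gpx4, Hmgb2, Ly6c2, Mx1, Mx2, Psme2 and Xist). Ly6c2 is in no list but belongs to the classical monocyte marker set, which was scored without it. For a list with at least 3 members at 5 CPM or more in 1 library, the median log2 fold was set against 10000 random lists of the same size, matched on mean expression in 25 bins. The percentile among them describes these 2 libraries and is not a test between treatments. A list stands out here when its percentile is under 2.5 or over 97.5. The counting interval of a median comes from 1000 Poisson redraws of the summed counts. Members at least 1.5-fold higher or lower were counted.

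The genes named in the text follow a rule. In Kupffer-like cells these are the 12 highest and 12 lowest log2 folds among genes with at least 20 CPM in 1 library and at least 100 UMIs in all. In monocyte-like clusters 6 each way were taken, and in other classes 3 each way. Genes whose CPM was under 5% of that in the highest class, in both libraries, were set apart as possible carry-over. Up to 10 genes at least 1.5-fold the same way in every compared class were named as library-wide. Each described list adds its 2 members with the largest fold of either sign at 20 CPM or more, and 11 Kupffer cell genes were named whatever their value. A few further list members are named as examples, chosen after their values were seen. Results on 1 compared cluster, 1 gene list and some single genes that the rule names are left out of the text, while counts over classes and lists include them. The groups, comparisons, marker sets, lists, naming rule and 29 alternatives were fixed before the data were examined, and 10 alternatives were added afterwards.

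Shares of Kupffer-like cells with a UMI of a gene were also computed after thinning each cell to 1700 UMIs, with 23 control and 163 metronidazole cells too shallow to use. TMM scaling came from edgeR 4.0.16 and size factors from DESeq2 1.42.0 in R 4.3.3. Other work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. The comparison was run on counts simulated with the UMI totals of the Kupffer-like class, drawn for each gene independently from a Poisson distribution. No single cells were simulated. The intervals assume the same distribution, so their coverage checks the calculation and not the spread between cells or mice. The 95% intervals held the simulated fold for 95.4% of 7181 unchanged genes and for 97.0% of 67 genes made 2-fold different. The added 5 CPM drew the median log2 fold of those 67 genes to 0.95, against 1.02 without it. Of 200 unchanged lists, 1.5% fell beyond the outer 2.5% of random lists on either side.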

Results

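The liver immune compartment was profiled by single-cell RNA measurement after 3 weeks of control or metronidazole drinking water. Metronidazole is an antibiotic that acts on anaerobic bacteria and some protozoa. The series title names macrophages, so Kupffer cells, the resident macrophages of the liver sinusoids, are treated as the main class. The control library held 5648 cells with a median of 1433 UMIs and 1020 genes per cell, and the metronidazole library 6012 cells with a median of 1206 UMIs and 895 genes. Each group is a single library from a pool of 3 mice, so no replicate check exists. The intervals given cover counting error only, not differences between mice. The labels give each library a batch tag that equals its library name, while samples of this assay are pooled before loading, so it is not known whether the tag marks a real batch. Any batch difference would coincide with the treatment.

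The first comparison asks how the make-up of the sorted liver immune cells differed between the treatments. Kupffer-like and B-like cells took larger shares in the metronidazole library, and T-, NKT- or innate lymphoid-like cells a smaller share. Kupffer-like cells were 19.3% (1157 of 5999 cells, interval 18.3 to 20.3) against 15.7% (883 of 5627 cells, 14.8 to 16.7) in the control library, a ratio of 1.23 (1.125 to 1.34). B-like cells were 9.65% (8.92 to 10.4) against 6.45% (5.82 to 7.12), a ratio of 1.496 with an interval of 1.31 to 1.71. The T-, NKT- or innate lymphoid-like cells were 34.4% (33.2 to 35.7) against 38.3% (37.0 to 39.6), a ratio of 0.900 (0.847 to 0.956). With clustering at resolution 2.0 it was 0.947 (0.888 to 1.01), an interval that includes 1. At that resolution, clusters scored highest as CD4 T cell (96 control and 65 metronidazole cells) and NKT cell (185 and 114) stayed unnamed. Those cells left the count, so this ratio does not cover the same cells. Within the T-, NKT- or innate lymphoid-like cells of the main clustering, cluster 3 was 8.03% against 11.02% of cells, a ratio of 0.729 (0.646 to 0.823). It was led by the granzyme gene Gzmb, the chemokine gene Xcl1 and Cd160. NKT-like cluster 2 was 12.02% against 11.8%. Monocyte-like cells were 9.10% against 8.26%, and their cluster 4, led by F13a1 and Fn1, was 4.98% against 3.54% (ratio 1.41, 1.17 to 1.69), while their cluster 12 was 4.12% against 4.73% (0.871, 0.730 to 1.04). The interval of the ratio included 1 for NK-like (0.977), cDC1-like (0.996), cDC2- or mature dendritic cell-like (1.12), plasmacytoid dendritic cell-like (1.15), monocyte-like (1.10), neutrophil-like (0.890), cycling (0.905), plasma-cell-like (1.34) and endothelial-like cells (0.616).

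These shares follow CD45 bead enrichment and a live CD45-positive sort, and median depth differed by class: 4125 UMIs in control and 3505 in metronidazole Kupffer-like cells, 868 and 881 in B-like cells, and 1012.5 and 911.5 in T-, NKT- or innate lymphoid-like cells. Cells of clusters with high doublet scores stayed unnamed and were 7.64% of control and 3.33% of metronidazole cells. Cluster 9 was the main part of them, with 315 control and 99 metronidazole cells, and with it counted as Kupffer-like the Kupffer-like ratio was 0.983. With at least 1000 UMIs and 500 genes required per cell, the ratio of plasmacytoid dendritic cell-like cells was 0.717 and that of NK-like cells 0.765.

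**Figure D1:**
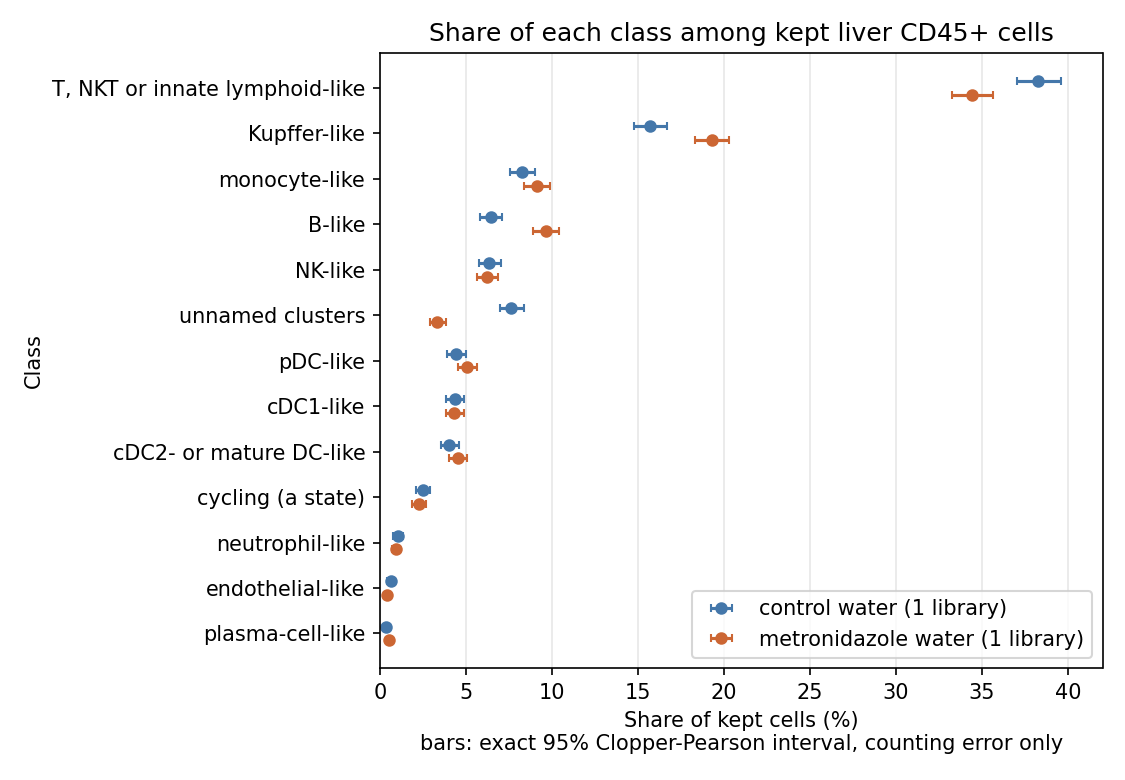
Share of each class among the kept cells of each library, in percent, with exact 95% Clopper-Pearson intervals for counting error, for control (blue) and metronidazole (orange). Kupffer-like cells were at 15.7% and 19.3% and B-like cells at 6.45% and 9.65%.

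The second comparison asks which genes and pathways differed within Kupffer-like cells. Interferon-gamma response, antigen presentation and chemokine genes were lower in the metronidazole library, while scavenger receptor, efferocytosis and lysosome genes were on balance higher. With the folds of other classes subtracted, the interferon-gamma, MHC class II and chemokine lists no longer stood out. Kupffer cell identity genes were on balance at similar levels in both libraries, though members such as Spic and Cd5l were higher. With 5 CPM added, and with library-wide genes and possible carry-over left out, the lowest log2 fold was that of Ptgis and the highest that of Cd36.

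Among the genes higher in metronidazole, Cd36, a scavenger receptor and fatty acid transporter (ENSMUSG00000002944, GRCm38 chromosome 5, 17781690 to 17888801), was at 280.02 against 121 CPM. That is 2.32-fold higher, with an interval of 2.08 to 2.59 from 1214 and 465 UMIs. Spic, a transcription factor of iron-recycling macrophages (ENSMUSG00000004359, chromosome 10, 88674772 to 88685015), was at 343 against 191 CPM, 1.80-fold higher (1.65 to 1.97). Hpgds, which makes prostaglandin D, was 1.83-fold higher (245 against 134 CPM), and Cd1d1, which presents lipids to NKT cells, 1.80-fold higher (104 against 57.4 CPM). Clec4b1, a C-type lectin gene, was at 54.4 against 23.6 CPM. The erythropoietin receptor gene Epor was at 24.4 against 8.83 CPM, Glis3 at 28.8 against 10.1 CPM, Ppid at 28.4 against 11.9 CPM and D1Ertd622e at 23.1 against 9.87 CPM. Hnrnpa2b1 (415 against 226 CPM) and Tent2 (189 against 101 CPM), which act on RNA, were also higher in 13 of 13 other classes.

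Among the genes lower in metronidazole, Ptgis, which encodes prostacyclin synthase (ENSMUSG00000017969, chromosome 2, 167191805 to 167240604), was at 49.8 against 142 CPM. That is 2.86-fold lower, with an interval of 2.44 to 3.36 from 216 and 548 UMIs, and Ptgis is also among the 10 genes that lead the unnamed cluster 9. Ptgis was lower in 9 of 13 other classes too, with a median log2 fold of -0.82 over the 13. Cxcl9, an interferon-gamma-induced chemokine that attracts T cells (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), was at 62.3 against 162 CPM, 2.59-fold lower (2.25 to 3.004). Cxcl9, Cxcl10 and Gbp5 are among the genes that lead cluster 19, which held 8.83% of control and 4.93% of metronidazole Kupffer-like cells. In cluster 0 alone, which held the others, the log2 fold of Cxcl9 was -0.62, against -1.31 in the class. A smaller fold there is built in, since Cxcl9 itself helps to define cluster 19, so the level per cell and the split between clusters are not separated. A Cxcl9 UMI was in 4.32% of metronidazole and 8.38% of control Kupffer-like cells (2.41% and 5.12% at 1700 UMIs per cell). In T-like cells, which were shallower, it was in 0 of 719 metronidazole and 0.702% of control cells. The chemokine gene Cxcl14 was at 7.84 against 23.6 CPM, Ltc4s, which encodes leukotriene C4 synthase, at 21.5 against 48.3 CPM, and the transporter gene Slco3a1 at 7.15 against 21.0 CPM. Krt80 was at 11.3 against 26.8 CPM and Ly6a, an interferon-inducible surface protein gene, at 20.1 against 42.6 CPM. The ferritin heavy chain gene Fth1 (1396 against 2740 CPM), the phosphatase gene Dusp2 (50.3 against 111 CPM), Fxyd5 (50.3 against 109 CPM) and the MHC class I gene H2-Q7 (68.5 against 135 CPM) were lower here and in 13 of 13 other classes. Cxcl9, Slco3a1, Krt80 and H2-Q7 were over the 5% carry-over limit in control alone, at 12.4%, 5.2%, 8.2% and 6.2% of their highest class. In metronidazole they were at 4.7%, 1.9%, 3.1% and 3.4%, so carry-over stays possible for them.

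**Figure D2:**
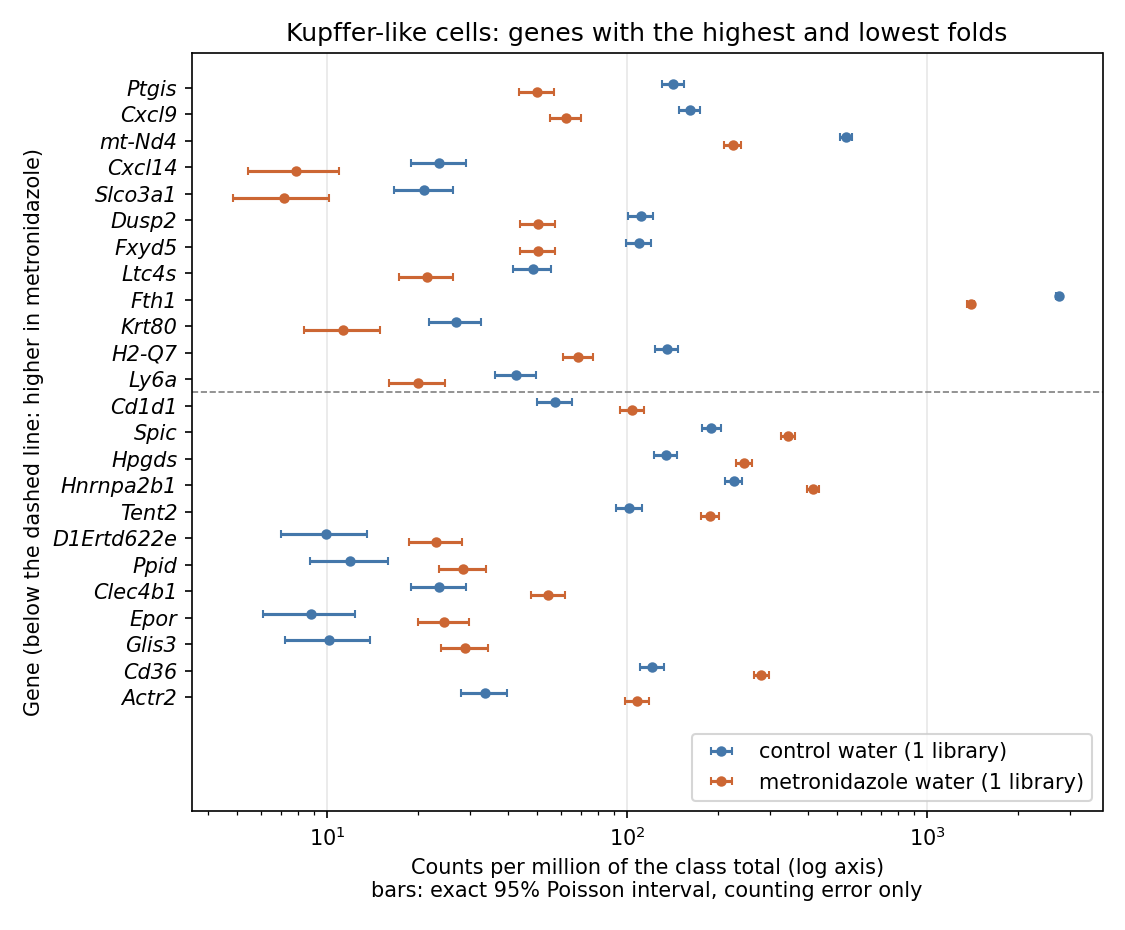
CPM of the Kupffer-like class total on a log axis for the 12 lowest and 12 highest folds, in control (blue) and metronidazole (orange), with exact 95% Poisson intervals. Cd36 was at 121 and 280.02 CPM and Ptgis at 142 and 49.8 CPM.

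The interferon-gamma response list had a median log2 fold of -0.26 (counting interval -0.33 to -0.18, percentile 0.00), with 16 of 20 members below 0 and 4 at least 1.5-fold lower, and in cluster 0 alone it was at -0.20 (percentile 0.01). Cxcl10, which shares the receptor of Cxcl9, was at 78.9 against 152 CPM. MHC class II presentation was at -0.34 (-0.44 to -0.25, percentile 0.00), with 8 of 12 members below 0. Its members Ciita, the master regulator of MHC class II genes that stands in both lists, H2-Eb1 and Cd74 were at 110.2 against 191, 585 against 932 and 2348 against 3590 CPM. H2-Ob, set apart as possible carry-over, was at 20.5 against 44.7 CPM. MHC class I presentation was at -0.27 (percentile 0.00), with 14 of 15 members below 0 and none by 1.5-fold. B2m, the light chain of MHC class I, was at 209.7 against 314 CPM and the immunoproteasome gene Psmb10 at 119 against 178 CPM. The chemokine list was at -0.22 (percentile 0.05), led by Cxcl9 and Cxcl14, with 14 of 18 members below 0. The NF-kB list was at -0.16 (percentile 0.16), where Il6 was at 13.4 against 23.6 CPM and Ccl4, possible carry-over, at 66.0 against 103 CPM. Type I interferon response was at -0.13 (percentile 0.14), with 20 of 28 members below 0. Its members Stat2 (251 against 394 CPM) and Trim30a (229 against 176 CPM) differed in opposite directions.

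Efferocytosis and scavenger receptors had a median of 0.15 (0.11 to 0.20, percentile 99.5), with 14 of 18 members above 0. In cells without lymphocyte or dendritic cell marker UMIs the median was 0.084 (93.0) and did not stand out. Beside Cd36, Mertk, a receptor for dying cells, was at 1124 against 880 CPM (1.28-fold higher, 1.22 to 1.34) and the scavenger receptor gene Marco at 1438 against 1183 CPM (1.22-fold, 1.17 to 1.26). Gas6, a ligand of Mertk, went the other way, at 11.1 against 20.3 CPM. The lysosome list was at 0.12 (0.06 to 0.15, percentile 99.2), with 17 of 25 members above 0. Lipa, which encodes lysosomal acid lipase, was at 386 against 266 CPM.

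Kupffer cell identity had a median of -0.02 (percentile 31.0), and its members Clec4f (7868 against 7996 CPM), Vsig4 (1163 against 1182 CPM) and Timd4 (739 against 787 CPM) were close to equal. Other members were higher in metronidazole. Spic was at 343 against 191 CPM, Cd5l, a secreted scavenger protein gene, at 7365 against 6201 CPM, and the potassium channel gene Kcna2 at 605 against 464 CPM. The bacterial sensing list was at 0.06 (percentile 85.8), with the lipopolysaccharide receptor gene Tlr4 at 121 against 116 CPM, its co-receptor gene Cd14 at 154 against 159 CPM, and Tlr13 and Tlr8 at 40.1 against 26.0 and 62.7 against 43.4 CPM. This list depended on the setting. It stood out at 0.15 (98.4) in cells thinned to equal depth and at 0.20 (99.97) with cluster 9 counted in. In cells without lymphocyte or dendritic cell marker UMIs it was at -0.061 (15.2). Among cytokines, Tnf was at 61.4 against 76.4 CPM, Il1b at 613 against 498 CPM and Il10 at 57.4 against 51.2 CPM. Microbe capture was at 0.00 (percentile 54.6), with C5ar1 at 40.6 against 59.998 CPM and Clec4n at 90.2 against 63.4 CPM. Alternative activation was at 0.11 (percentile 96.0), with Cd200r1 at 67.6 against 44.9 CPM and Pparg at 30.7 against 21.0 CPM. LXR targets were at 0.10 (percentile 92.9), with Abcg1 at 134 against 181 CPM. The lipid-associated macrophage list was at 0.03 (64.0), iron and heme handling at 0.05 (81.3) and NRF2 at 0.06 (83.4), with Sod1 at 163 against 114 CPM and Cat at 241 against 175 CPM. Cholesterol biosynthesis was at 0.02 (59.5), complement at -0.00 (46.7), bile acid and related receptors at 0.03 (59.6), oxidative phosphorylation at 0.02 (64.6), neutrophil maturity at -0.02 (40.3) and endothelial and stellate transcripts at 0.05 (73.4). Glycolysis was at -0.10 (7.52) and cell cycle at -0.13 (7.51). The sex-linked list had 0 measured members and was given no median.

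Transcripts of other cells were lower in metronidazole Kupffer-like cells as well. Of genes with folds as far from 0 as those named, 19 were set apart as possible carry-over, and 19 of 19 were lower, among them the T cell kinase gene Lck (6.92 against 22.3 CPM) and Sept1 (14.3 against 42.9 CPM). The cytotoxic lymphocyte list was at -0.60 (percentile 0.00), the naive lymphocyte list at -0.34 (0.685) and the hepatocyte list at -0.13 (1.72). These calls depended on the setting: the cytotoxic list was at 0.12 for members of at least 50 CPM, and with the other classes subtracted it was at -0.23 (3.625), the naive list at -0.029 (47.4) and the hepatocyte list at 0.17 (98.95). In cells without foreign marker UMIs the naive list was at -0.17 (11.4) and the hepatocyte list at 0.0042 (44.6). The immediate early and heat shock list, which responds to tissue dissociation, was at -0.10 (1.29), but at -0.029 (26.5) in cells thinned to equal depth and -0.082 (3.64) in cluster 0 alone, where it did not stand out. It included the heat shock genes Hsph1 at 42.2 against 68.8 CPM and Dnajb1 at 98.5 against 152 CPM. No UMI of 52 lymphocyte and dendritic cell markers was seen in 62.7% of metronidazole and 42.0% of control Kupffer-like cells, which depth alone would move the same way, and in 77.9% (75.2 to 80.4) and 66.0% (62.8 to 69.2) of those thinned to 1700 UMIs.

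At an equal depth of 1700 UMIs per cell, 31.5% of metronidazole and 17.3% of control Kupffer-like cells held a Cd36 UMI, against 48.2% and 30.8% without thinning. For Ptgis these shares were 6.94% and 20.3% (13.4% and 35.9% without thinning), and for Spic 36.1% and 21.9% (51.8% and 40.5%). T-like cells, which should lack these genes, had medians of 783 and 878.5 UMIs. In them, Cd36 and Ptgis UMIs were each in 0 of 719 metronidazole and 0.140% of control cells, and Spic UMIs in 0.278% and 0.140%. The 0 of 719 allows a share of up to 0.512% with a UMI by the exact interval, or 0.417% by a limit of 3 cells of 719. A Tnf UMI was in 7.95% and 9.65% of thinned Kupffer-like cells, no more than the 8.48% and 10.5% of T-like cells, which make Tnf themselves. With each gene's median fold over the other 13 classes subtracted, type I interferon was at 0.061 and immediate early at 0.20 in Kupffer-like cells. Interferon-gamma was then at -0.089 (percentile 4.34), MHC class II at -0.077 (6.61), chemokines at -0.12 (3.74) and NF-kB at -0.068 (8.78). Much of the lower level of these lists was thus shared with other classes. For MHC class II this held only for classes with its members under the Kupffer-like level, 8 of which were below 0. The 4 classes at or above that level had medians above 0. MHC class I presentation stayed at -0.18 (0.02) and still stood out, but RNA of other cells was not tested as its source. Without the subtraction, it was at -0.48 with cluster 9 counted in and at -0.25 in cells without foreign marker UMIs. The same subtraction gave 0.89 for Kupffer cell identity, 0.53 for efferocytosis, 0.45 for complement, and 0.24 for both alternative activation and LXR targets, all at percentiles of at least 99.7. These lists were lower in most other classes, so the 0.53 is part of a general rise under that setting and does not set efferocytosis apart. Efferocytosis was at 0.084 (percentile 93.0) in cells without foreign marker UMIs, type I interferon at -0.033 (25.7) with cluster 9 counted in, and NF-kB at -0.078 (8.18) with cells thinned to equal depth, which leaves out the 23 control and 163 metronidazole cells that were too shallow, so these lists did not stand out there.

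The third comparison asks in which other classes the same genes and lists differed. The interferon-gamma list was lower in monocyte-like cluster 4 (median -0.64, percentile 0.00, 11 of 19 members at least 1.5-fold lower), with the guanylate-binding protein gene Gbp5 at 43.2 against 111 CPM and Socs1 at 15.1 against 37.1 CPM. In the same cluster MHC class II presentation was at -0.50 (percentile 0.01) and type I interferon response at -0.33 (0.00), with Ciita at 80.0 against 170 CPM, Cd80 at 64.8 against 34.6 CPM and the antiviral gene Rsad2 at 38.9 against 133 CPM. The genes with the lowest folds there included the interferon signalling genes Stat2 (197 against 467 CPM), Ikbke (246 against 524 CPM) and Pml (102 against 220 CPM), with Ndst1 and Atp2a3 and the library-wide mt-Nd4. Stat2 was lower in every compared class, so its fold is not particular to this cluster. The highest were Cdc42 (162 against 69.2 CPM), Hnrnpa2b1, Taf4, the cholesterol esterification gene Soat1 (171 against 74.1 CPM), Acbd3 and Mlec. Monocyte-like cluster 12 had its highest folds at the mannose receptor gene Mrc1 (278 against 104 CPM), Cadm1, Adgb, the heme oxygenase gene Hmox1 (437 against 198 CPM), Atp6v0a1 and the lysosomal protease gene Lgmn (339 against 162 CPM). Its lowest were AA467197 (85.4 against 323 CPM), Hic1, Kcnn4, the vitamin D receptor gene Vdr (73.5 against 169 CPM), mt-Nd4 and Spag7, and glycolysis was at -0.40 (percentile 0.01), with Pgk1 at 7.12 against 27.3 CPM (3 and 16 UMIs, ratio 0.260, 0.0486 to 0.910) and Slc16a3 at 114 against 198 CPM. Cluster 12 is itself led by Ptgs2, Cxcl9, Cxcl10 and Cxcl2. Possible carry-over from Kupffer cells was lower in cluster 4 too, with Cd5l at 97.3 against 289 CPM.

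In cDC2-like cells MHC class II presentation was higher instead, at 0.27 (interval 0.13 to 0.30, percentile 99.8), with 11 of 13 members above 0 and the costimulatory gene Cd86 at 119 against 56.8 CPM. Nr4a3 (248 against 91.7 CPM), Adam23 and Adam19 had the highest folds there. Hsph1 (91.2 against 249 CPM), the metallothionein gene Mt1 (143 against 373 CPM) and the stress gene Ddit4 (95.9 against 231 CPM) had the lowest. In cDC1-like cells type I interferon response was at -0.62 (percentile 0.00, 15 of 27 members at least 1.5-fold lower), with Ddx58 at 2.61 against 20.8 CPM (2 and 18 UMIs, ratio 0.126, 0.0141 to 0.525) and Oas3 at 15.7 against 50.9 CPM. Their cell cycle list was at 0.52, above all 10000 matched random lists, with the cyclin genes Ccnb2 at 107 against 24.3 CPM and Ccna2 at 61.4 against 20.8 CPM. Apol7c was at 116 against 40.5 CPM there, Dusp5 and Adcy4 were lower, and the creatine kinase gene Ckb was at 124 against 284 CPM. In plasmacytoid dendritic cell-like cells the immediate early list and the cell cycle list both had a median of -0.78 (percentiles 0.00 and 0.02), with Ier2 at 91.4 against 282 CPM and Top2a at 7.03 against 37.4 CPM (2 and 11 UMIs, ratio 0.188, 0.0203 to 0.863). Fth1 (932 against 2296 CPM) and Ctsw were lower in them as well, and Vamp8 (288 against 136 CPM), Pqbp1 and Ptma higher.

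In B-like cells the immediate early list was at -0.35 (percentile 0.00) and type I interferon response at -0.40 (0.01). Their lowest folds were at the immunoglobulin gene Ighg3 (57.5 against 203 CPM), Cbfa2t3 (113 against 353 CPM) and the stress-induced Atf3 (69.7 against 205 CPM), and their highest at Elavl1, Srsf5 and H2-DMb2 (159 against 76.6 CPM). In NK-like cells 24 of 24 immediate early members were below 0, with a median of -0.50, and Fosb was at 213 against 475 CPM and Hsph1 at 84.1 against 245 CPM. Cd53, Ndfip1 and mt-Nd3 had the highest folds in NK-like cells. In NKT-like cluster 2 the chemokine gene Ccl4 was at 35.1 against 109 CPM and Ddit4 was lower, with Fadd and Prdm2 higher. In NKT-like cluster 3 the interleukin 18 receptor gene Il18r1 was at 212 against 93.9 CPM and Cdc42 and Hnrnpa2b1 were higher, with Stat2 at 44.8 against 117 CPM and Hsph1 and Cdk10 lower. In T-like cluster 14 Furin was at 190 against 665 CPM, Zeb2 was lower and Dhx36 and Hnrnpa2b1 higher. In T-like cluster 5 Pabpc1 and mt-Nd3 were higher, Runx1 and Fth1 were lower, and nuclear oxidative phosphorylation genes were at 0.35 (percentile 99.4). The genes Trbv29 in cluster 2, Themis in cluster 5 and Foxp3 in cluster 14 also met the naming rule. They are among the genes that lead those clusters, so the level per cell and the make-up of the cluster are not separated for them. In cycling cells Hspa1a (189.6 against 522 CPM) and Zeb2 were lower, and Ipo5 and Mybl2 (276 against 134 CPM) higher. This cluster is a state that holds more than 1 cell type, so Pax5, a B cell marker that was higher there, may describe its make-up, as may the other genes.

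Across the 13 classes other than Kupffer-like cells, several lists had a median below 0 in most, but not all of these stood out. MHC class I presentation was below 0 in 13 of 13 and stood out as lower in 7, immediate early and heat shock in 12 and 11, type I interferon response in 12 and 9, and interferon-gamma response in 10 and 3. Kupffer cell identity was below 0 in 13 of 13 and stood out in 11 of them, as low as -1.36 in cycling cells, although Kupffer-like cells themselves were at -0.02. The library-wide genes, at least 1.5-fold the same way in 14 of 14 classes, were the mitochondrial complex I gene mt-Nd4 (282 against 692 CPM over all cells) and the actin-nucleating Arp2/3 gene Actr2 (95.9 against 32.2 CPM). In Kupffer-like cells these were at 225 against 535 and 108 against 33.5 CPM. Several other named genes went the same way in every compared class, though not by 1.5-fold in each. Stat2, Cdk10, Ddit4, Fth1, Runx1 and Cbfa2t3 were lower, and Cdc42, Hnrnpa2b1 and mt-Nd3 higher. Their folds are thus not particular to the classes they were named in. The mitochondrial gene mt-Nd3 had a median log2 fold of 0.75 over classes other than NK-like cells, opposite to mt-Nd4, and the cause was not tested.

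**Figure D3:**
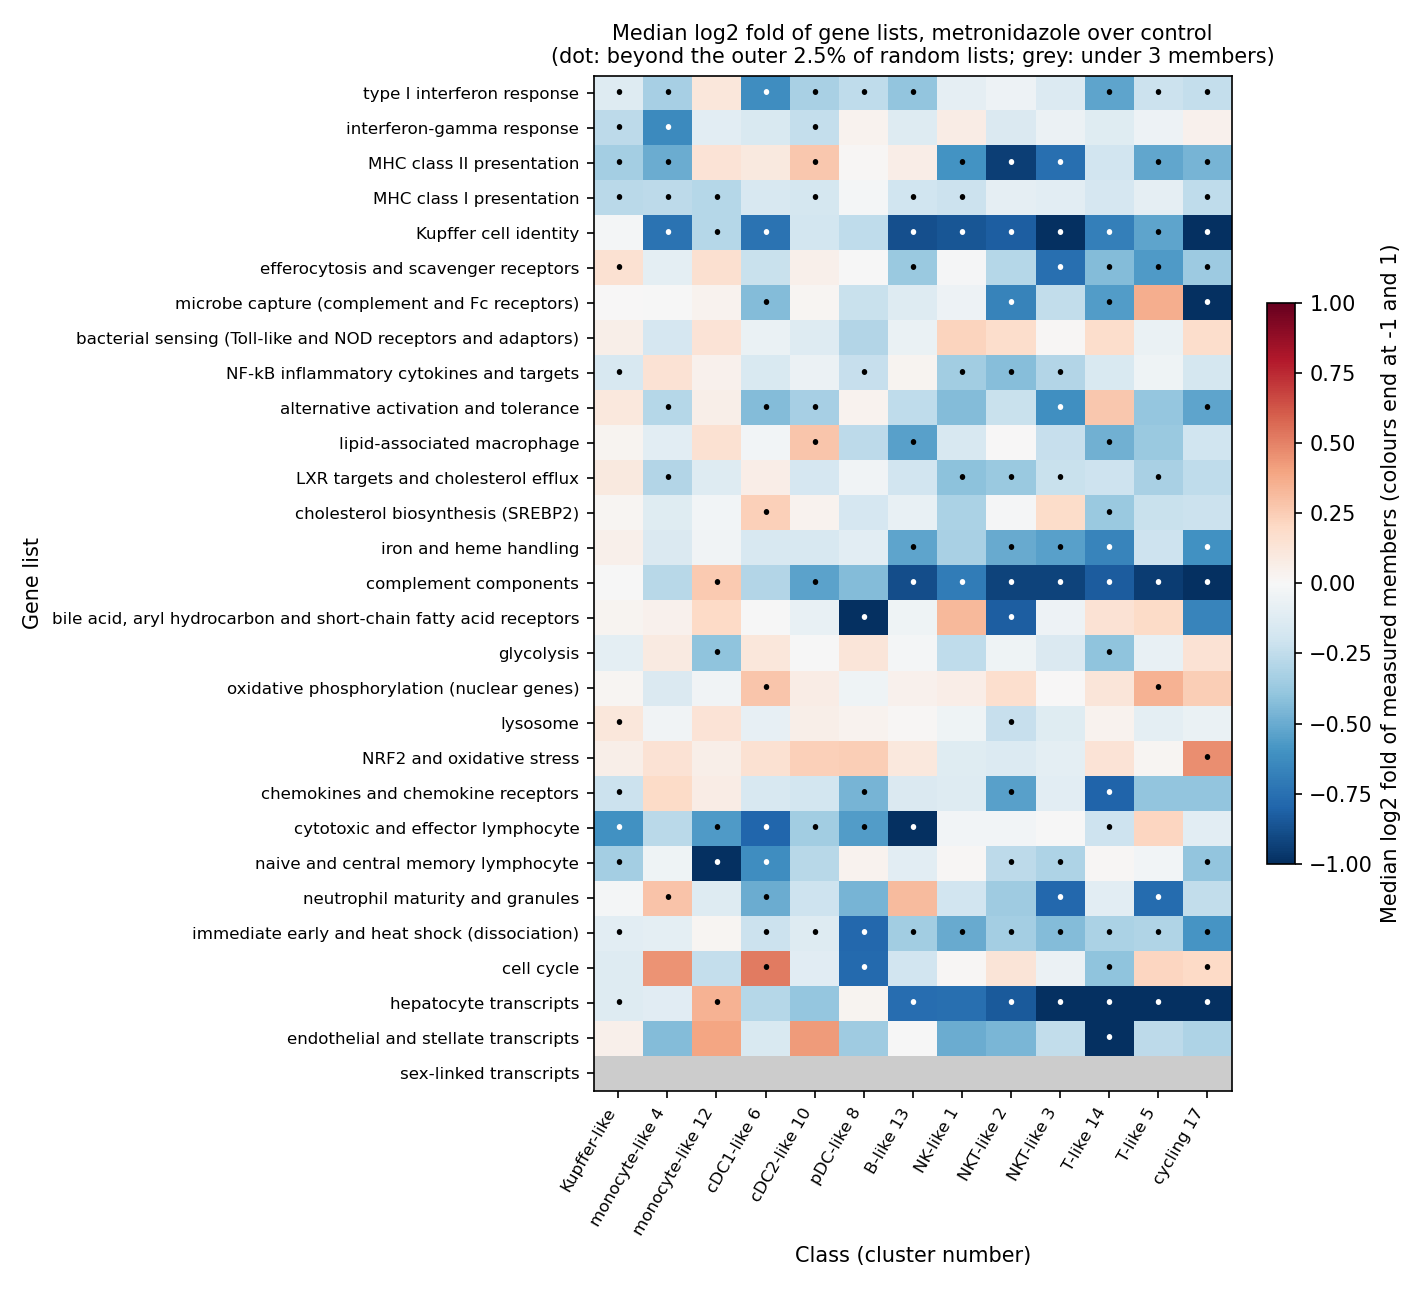
Median log2 fold, metronidazole over control, of each described gene list (vertical) in each described class (horizontal), with colours that end at -1 and 1. A dot marks a median beyond the outer 2.5% of matched random lists, and grey a list with under 3 measured members. The interferon-gamma median was -0.26 in Kupffer-like cells and -0.64 in monocyte-like cluster 4.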

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

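Of the tests given here, those on cluster 9, on RNA of other cells in Kupffer-like cells, on shifts of the whole library and on free RNA were chosen only after the result was seen, while those on shallow cells and on joined cells were set before. MHC class II presentation stood out in opposite directions, with a median log2 fold of -0.50 in monocyte-like cluster 4 and 0.27 in cDC2-like cells, and the difference was not tested. The cell cycle list did the same, at -0.78 in plasmacytoid dendritic cell-like cells and 0.52 in cDC1-like cells, and that difference was not tested either. The mast cell transcripts Cma1, Tpsb2, Mcpt4 and Cpa3, which no comparison above uses, had 116 UMIs in the 200 unnamed metronidazole cells and 4 UMIs in the 430 unnamed control cells, and 115 of the 116 were in 1 cell.

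The Kupffer-like share was 1.23 times as large in the metronidazole library. Loss of shallow cells is argued against: control cells thinned to 85.0% of their UMIs and held to the lowest deposited total gave a Kupffer-like share of 16.3% (15.3 to 17.3), within the control interval and below the lower bound of 18.3% in metronidazole. Cluster 9 stays open as a candidate explanation, because with it counted as Kupffer-like the ratio was 0.983 (0.908 to 1.07). Of its cells, 99.7% in control and 98.0% in metronidazole held a Kupffer cell marker UMI, and 73.3% and 41.4% a T or NK marker UMI, against 7.45% and 3.36% in Kupffer-like cluster 0. Holding a marker UMI does not identify Kupffer cells at its median depth of 5957 control and 4275 metronidazole UMIs. Carry-over can give such a UMI, since 40.4% of control lymphocyte-like cells held one too. By marker score cluster 9 was highest as erythroid cell (0.84) and then hepatocyte (0.67), and Hba-a2 and Hbb-bs led it. An effect of metronidazole on Kupffer cell numbers stays open and untested, as does any batch difference.

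The interferon-gamma and MHC class II lists were lower in metronidazole Kupffer-like cells. A shift of the whole library is argued against for MHC class II: in the 4 other classes that held its members at least at the Kupffer-like level, the medians were 0.065 (-0.029 to 0.15) in B-like, 0.099 (0.019 to 0.18) in cDC1-like and 0.27 (0.13 to 0.30) in cDC2-like cells and 0.14 (0.027 to 0.22) in monocyte-like cluster 12, against -0.34 (-0.44 to -0.25) in Kupffer-like cells. RNA of lymphocytes, dendritic cells and monocytes in control Kupffer-like cells and a difference of Kupffer cells themselves cannot be told apart, because the answer turned on how markers of those cells were grouped. As a percent of the control level in the highest other class, the median drop was 4.61% (3.19 to 5.99) for interferon-gamma and 3.54% (2.16 to 4.23) for MHC class II members. The median drops of foreign markers summed to 1.49% (1.05 to 2.27) with marker sets grouped by lineage, below both, but to 3.55% (2.58 to 5.54) with each of 13 sets counted on its own. Leaving out cells with foreign marker UMIs does not settle it, since the cytotoxic lymphocyte list was at -0.73 in the cells left. That median rests on 6 members, against 11 in all Kupffer-like cells, so it does not cover the same genes. For interferon-gamma a shift of the whole library stays open, since the 2 other classes at that level were at -0.24 (-0.43 to -0.052) in cDC2-like cells and -0.10 (-0.26 to -0.011) in monocyte-like cluster 12, against -0.26 (-0.33 to -0.18). With the other classes subtracted, interferon-gamma was at -0.089 (-0.18 to -0.034, percentile 4.34) and MHC class II at -0.077 (-0.13 to -0.016, percentile 6.61). These calls ended because other classes were lower too: 10 of 13 had an interferon-gamma median below 0, from -0.64 to 0.07, and 8 of 13 an MHC class II median below 0, all 8 among the 9 classes that held its members under the Kupffer-like level. A response of Kupffer cells to the treatment stays open and untested, and any batch difference would coincide with the treatment.

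Kupffer cell markers were lower in metronidazole lymphocyte-like cells, at 278 against 641 CPM, and a UMI of them was in 21.3% of 3018 metronidazole and 40.4% of 2875 control cells. Whole Kupffer cells joined to a few lymphocytes are argued against as the sole cause, since without the 5% of cells with most marker UMIs the ratio was 0.400 (0.360 to 0.444), against 0.433 with all cells. Free Kupffer cell RNA stays open: 12 of 12 markers were lower as a percent of their Kupffer-like level, with medians of 0.883% in metronidazole and 2.34% in control cells. This count cannot decide it, since it largely restates the pattern where Kupffer-like levels were close to equal, as for Clec4f and Vsig4. The percentages ranged from 0.473% to 1.96% and from 1.48% to 3.26%, so a common source in the control library may account for them. No biological explanation was tested.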

How the results depend on the processing

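The alternatives that count cluster 9 or 11 in, leave out the highest 10% of doublet scores, use cells without foreign markers or use cluster 0 alone were added after seeing the data. Of the share ratios under the alternatives, 59 kept their value within the interval, 4 moved and 1 reversed. For the 8 main lists these counts were 110, 17 and 1, for other lists 279, 34 and 4, and for named genes 461, 64 and 0. A result counted as reversed only if it was a list that stood out, a share whose interval left out 1 or a gene named for its fold, and it changed direction. Of the genes named whatever their value, Clec4f (-0.023), Timd4 (-0.089), Vsig4 (-0.024) and Cd14 (-0.043) were at 1.10, 0.91, 0.68 and 0.52 with the other classes subtracted and above 0 with cluster 9 counted in, and Tlr4 (0.056) and Il10 (0.15) were at -0.015 and -0.011 in thinned cells. The lowest value of Tlr4 under any alternative was -0.061. Cd36 stayed between 0.95 and 1.32 and Ptgis between -1.53 and -0.61. With at least 1000 UMIs and 500 genes the ratio was 1.36 for Kupffer-like, 0.717 for plasmacytoid dendritic cell-like, 0.765 for NK-like and 0.806 for T-, NKT- or innate lymphoid-like cells. At resolution 2.0 the last was 0.947 (0.888 to 1.01), with 1 inside the interval. Clusters scored highest as CD4 T cell and NKT cell stayed unnamed there and left the count. With clusters 9 and 11 counted in, the Kupffer-like ratio was 0.983. With the other classes subtracted, medians were 0.89 for Kupffer cell identity, 0.53 for efferocytosis, 0.45 for complement, 0.24 for alternative activation and for LXR targets, 0.061 for type I interferon (reversed), -0.089 for interferon-gamma, -0.077 for MHC class II, -0.18 for MHC class I, 0.18 for lysosome, -0.12 for chemokines, -0.23 for cytotoxic, -0.029 for naive lymphocyte genes, 0.20 for immediate early (reversed) and 0.17 for hepatocyte genes (reversed). With cluster 9 counted in they were 0.26 for efferocytosis, -0.23 for NF-kB, -0.033 for type I interferon, -0.34 for interferon-gamma, -0.48 for MHC class I and 0.18 for lysosome. In cells without foreign markers they were 0.084 for efferocytosis, -0.25 for NF-kB, -0.42 for interferon-gamma and 0.0042 for hepatocyte genes (reversed). The mean over cells gave -0.20 for type I interferon, cluster 0 alone -0.39 for chemokines and -0.62 for Cxcl9 (main value -1.31), and members of at least 50 CPM 0.12 for cytotoxic genes (reversed). The cause was not tested, except that subtraction removes what other classes share and that naming left cells out at resolution 2.0. The median log2 fold of all genes was 0.0082 with TMM and 0.011 with size factors. No paired analysis was possible because each group is 1 pool. Depth limits genes with few UMIs most.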

Other observations

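The test on Ifng was chosen only after the result was seen. Over all kept cells, Ifng, the interferon-gamma gene, was at 246 against 332 CPM (0.741, 0.706 to 0.778). T-, NKT- or innate lymphoid-like cells were 34.4% of metronidazole and 38.3% of control cells, so this value mixes level per cell and make-up.

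Cells with a UMI of the cell cycle genes Mki67, Top2a or Rrm2, chosen after their values were seen, were 27.8% (22.4 to 33.7) of metronidazole and 25.8% (20.4 to 31.8) of control cDC1-like cells, with median depths of 2564 and 3111 UMIs. Thinned to 1400 UMIs per cell, with 26 metronidazole and 9 control cells too shallow to use, they were 22.7% (17.5 to 28.7) and 20.9% (15.8 to 26.6). In plasmacytoid dendritic cell-like cells, with median depths of 813 and 997 UMIs, they were 2.62% (1.14 to 5.10) and 2.41% (0.889 to 5.17), and 1.64% (0.534 to 3.78) and 2.01% (0.655 to 4.62) thinned to 500 UMIs, from 5 cells each. In T-like cells, with median depths of 783 and 878.5 UMIs, they were 5.01% (3.53 to 6.86) and 7.58% (5.75 to 9.78), and 2.79% (1.71 to 4.28) and 4.65% (3.22 to 6.47) thinned to 500 UMIs, with 2 cells of each library too shallow. The intervals overlap in all 3 classes, and these counts are too few to show whether such cells differed.

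A hypothesis for the lower interferon-gamma response in Kupffer-like and monocyte-like cells is less Ifng transcript in lymphocytes. In NK-, NKT- and all T-like cells together Ifng was at 944 against 1164 CPM, a ratio of 0.811 (0.769 to 0.855). That fold was at percentile 7.0 among 200 genes of like expression, so less Ifng and the general spread of genes between these libraries cannot be told apart, and the hypothesis stays open. The make-up of the pooled lymphocytes was not held equal either: cluster 3, led by Gzmb, was 8.03% of metronidazole and 11.02% of control cells.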
